A study of Drosophila melanogaster with 8 samples.

How the data were processed

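The series measured accessible chromatin by ATAC-seq, in which Tn5 transposase inserts adapters into open DNA, in Drosophila melanogaster embryos. It holds 8 libraries in 4 groups of 2 replicates: wild type (WT) and embryos with mislocalized IntS11, each collected at 1 to 1.5 h and at 2.5 to 3 h. IntS11 is the endonuclease subunit of the Integrator complex. The group of each library was taken from its title. Every title, WT or mutant, holds the words IntS11 mislocalized, so placing the mislocalization in the mutant alone was an inference. The labels do not say whether the replicates were separate collections of embryos, so permutation p-values measure only the spread between these libraries, which may be technical. Fisher's exact p-values use no spread between libraries.

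Each deposited list belongs to 1 library, so the peaks were called per sample and not on pooled samples. The submitters' processing notes name the dm6 genome build, Trimmomatic 0.39, Bowtie2 2.2.5, SAMtools 1.18, MACS2 2.2.7.1 and deepTools 3.5.1. The settings of these tools, including any shift of reads for the 2 cuts of the transposase and the handling of duplicates, are not given in the sources used here. The deposited lists hold 3 columns per peak, the chromosome, the start and the end, and were used as position lists in base pairs. They carry no count, fold enrichment, p-value or summit, so the sequencing depth of each library is unknown, and no interval or detection limit was set from it. A stretch outside a peak is one that was not called, which does not show that it was closed. In every library the shortest peak lay 1 bp below the smallest gap between peaks, and this length differed between libraries from 100 to 156 bp, so the shortest peak and the bridged gap were not the same in all libraries.

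All coordinates are dm6, 1-based. Gene positions came from a RefSeq gene table of the Release 6 assembly, the one that dm6 holds, with 17807 genes of which 13946 are protein coding. The table gives gene starts and ends without strand, transcripts or exons. A peak at a gene end was therefore a peak with at least 1 bp within 250 bp of either end of a gene's annotated span. This replaced the promoter, 250 bp either side of any transcript start, that had been set before the data were examined. It counts 3′ ends as well as 5′ ends, and 1 peak between neighbouring genes counts for both. Whether a region inside a gene was exonic or intronic was not analysed here.

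Peaks of all 8 libraries that overlapped by at least 1 bp were merged into 38545 regions. A region counted as called in a library where at least 1 bp of a peak of that library lay in it. In a comparison of 2 groups, a region was lost when both libraries of the first group called it and neither of the second did, gained in the reverse case, and kept when all 4 called it. Genes were classed the same way by their gene-end peaks. The same counts were made for the other 2 splits of the same 4 libraries. Replicates were compared with the Jaccard index, the shared covered length divided by the total covered length. No pair of libraries held the same list.

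Values per library were compared with two-sided exact permutation tests of the difference of group means. A window has 6 arrangements of 2 against 2 libraries, so p cannot fall below 0.333. Both windows together, with genotypes permuted within windows, have 36 arrangements, so p cannot fall below 0.0556, and no such test could pass 0.05. Benjamini-Hochberg adjustment covered 24 tests, for 6 values in each window, in both and for the difference between windows. Counts of regions or genes were compared with two-sided Fisher's exact tests, with adjustment over 36 tests of region classes and over 40 tests of gene lists per comparison. Fisher's tests treat regions and genes as independent, and they compare these libraries without a term for the spread between replicates. The background of a list test was the lost and kept genes, or the gained and kept genes. Odds ratios pooled over 20 classes of peak width used the Mantel-Haenszel estimate.

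The lists of 20 gene groups, the comparisons and the rule for named items were written before the data were examined. The lists were early zygotic, gap and terminal, pair-rule and segment polarity, Hox, dorsoventral patterning, snRNA, replication-dependent histone, ribosomal protein, tRNA, snoRNA, Integrator subunits, heat shock, promoter and chromatin factors, maternal patterning, germline, hemocyte with fat body and yolk, muscle, neural, follicle cell and gut digestive enzymes. Of all their symbols, 1 (nos) was not matched. Histone, tRNA, snRNA and snoRNA genes occur in near-identical copies, so reads may be shared between copies, and a peak near one copy is uncertain. The rule named IntS11, the 10 lost and 10 gained regions that ranked highest in each main comparison, and list members lost or gained, up to 6 per list. The ranking was to be by fold enrichment, which the lists do not hold, and mean peak width in the 2 calling libraries took its place. A width in a gene list is that of the widest peak at the gene's ends.

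Tests of sequence motifs, stricter peak thresholds, equal list lengths by significance and regions around summits had been planned and were not run, since no sequence, scores or summits were used here. The alternatives set before the data were examined and run are main chromosome arms only, peaks within 100 bp merged, a peak covering at least 50% of a region, gene-end windows of 100 and 500 bp, replicate number as a block, and each library left out in turn. Chosen after seeing the data were a common shortest peak and bridged gap of 160 bp, peaks of at least 200 bp, equal list lengths by width, and list members with a peak anywhere in the gene or within 2000 bp. Also chosen after seeing the data were list tests for the changes with time, list tests on separate regions, tests of X-linked and intergenic regions, direct comparisons of lost with gained regions, regions that separated the genotypes in both windows, the map around IntS11, the width-matched sets, regions that WT had at both ages and regions within 1 Mb of IntS11. Counting was tested on simulated lists: 200 regions were removed from slightly shifted copies of both WT lists of a window. Then 200 were called lost and 0 others were, among 29812 regions at 1 to 1.5 h and 21321 at 2.5 to 3 h. The copies held no spread between replicates. This checked the counting only, not false losses between real libraries. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.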

Results

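Accessible chromatin was mapped by ATAC-seq in Drosophila melanogaster embryos at 1 to 1.5 h and at 2.5 to 3 h. Wild-type (WT) embryos were set against mutant embryos, taken to be those in which IntS11, the endonuclease subunit of the Integrator complex, was mislocalized. Integrator cleaves nascent RNA near promoters and at snRNA genes. There were 2 libraries in each of the 4 groups, and each library was a list of peaks. The lists held 23815 and 25201 peaks in WT and 15569 and 18706 in the mutant at 1 to 1.5 h. At 2.5 to 3 h they held 18440 and 19002 peaks in WT and 19035 and 19995 in the mutant. The lists give positions only, so the sequencing depth is unknown, and a region without a peak was not called rather than shown to be closed.

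The IntS11 locus itself (gene 43506, dm6, chromosome 3R, 29745337 to 29747513) separated the genotypes in every library. A region at 29745279 to 29745833, at one end of IntS11 and within the antisense RNA gene asRNA:CR46109, was called in 4 of 4 WT libraries and in 0 of 4 mutant libraries. A region at 29746418 to 29747371, inside IntS11 up to its other end, was called in 0 of 4 WT libraries and in 4 of 4 mutant libraries. Its peaks were 907 and 947 bp wide in the mutant at 2.5 to 3 h, and at 1 to 1.5 h each mutant library held 2 shorter peaks there. The neighbouring gene ATPsyngamma was called in all 8 libraries, but its mutant peaks began at 29747687 to 29747852 and ended by 29748468. The WT peaks there began at 29748067 or later, and the last in each library ended at 29748880 to 29748892. The labels do not describe the mutant allele, and an edited locus would also shift mapped positions, so these peaks were not read as a change in accessibility. This map was drawn after the data were seen.

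**Figure D1:**
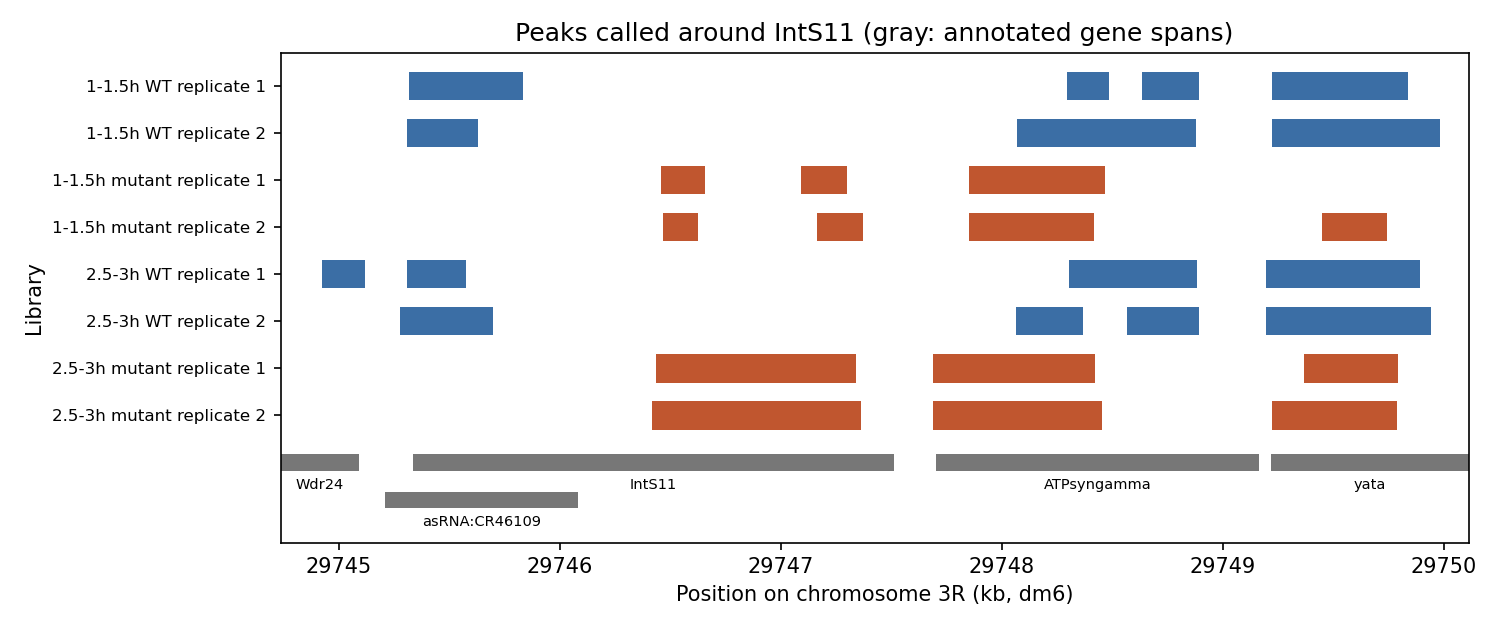
Peaks of the 8 libraries along chromosome 3R around IntS11 (x axis, dm6 position), with the genes annotated there drawn as bars. The WT peaks lie at one end of IntS11 and the mutant peaks lie inside the gene and at its other end. The mutant allele is not described in the labels, and an edited locus would also shift mapped positions.

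The comparison of mutant with WT embryos at 1 to 1.5 h addressed accessibility before the main wave of zygotic transcription. Mutant embryos had fewer and narrower peaks. Gene ends held 27.2% of lost and 44.2% of kept regions. They held 27.5% of all WT peaks, but this share includes peaks that the other replicate did not call. It is therefore not set against the shares of regions. Pooled over classes of WT width, the odds ratio of loss was 0.739 for gene ends (95% interval 0.677 to 0.808), so regions there were lost less often. The patterning genes hb, Kr, tll, eve, ftz, zen and sna kept their gene-end peaks, while nkd, ush and sog lost theirs, and none of the gap, pair-rule, Hox and dorsoventral lists passed a test alone. Peaks at the gene ends of Dref, Tbp, BEAF-32, Mlc2 and some ribosomal protein genes were lost, as were wide peaks inside Mi-2, psq, E23 and Hr4. As groups, neither ribosomal protein genes, which lost 18.6% against 29.0% of other genes, nor promoter and chromatin factors passed a test of loss.

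**Figure D2:**
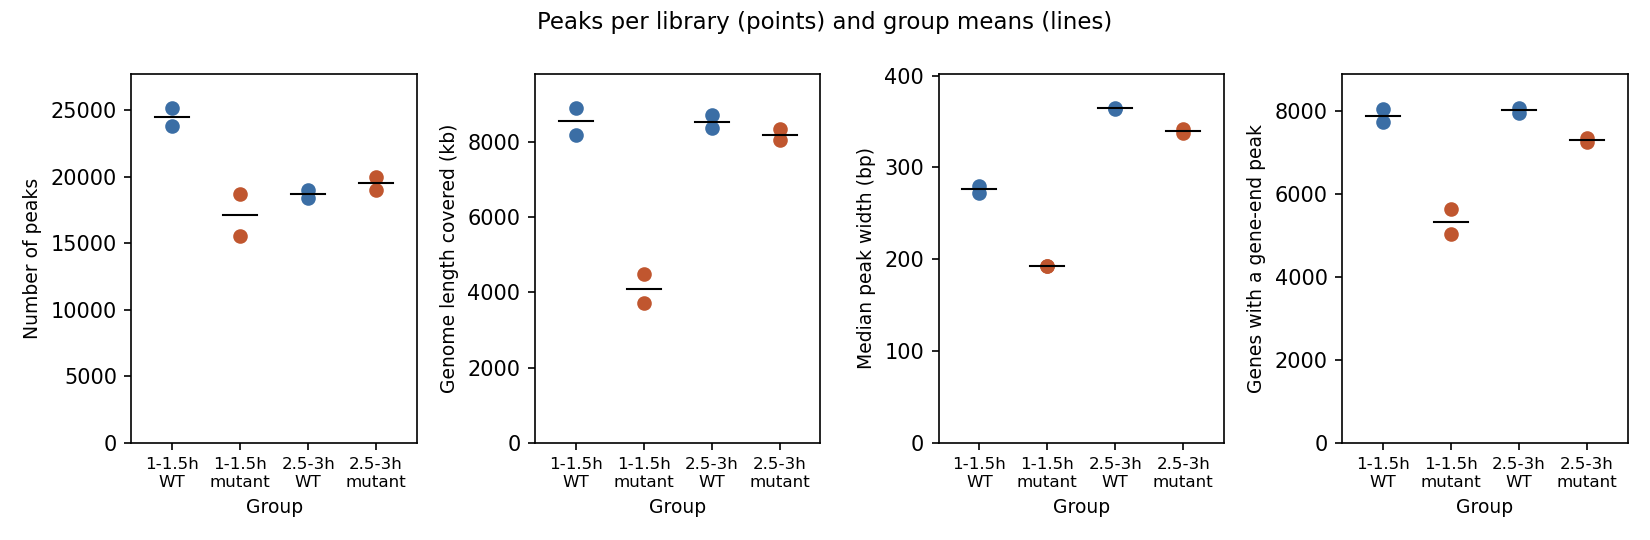
Number of peaks, covered length, median peak width and number of genes with a peak at a gene end in each library (points), with group means (lines). The 1 to 1.5 h mutant libraries lie below both WT libraries of that window in each panel, with 15569 and 18706 peaks against 23815 and 25201.

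The mean number of peaks was 17137.5 ± 2218 (SD, n = 2) in the mutant and 24508 ± 980 in WT at 1 to 1.5 h, or 69.9% of WT. Peaks covered 4099 ± 547 kb in the mutant and 8551 ± 512 kb in WT, or 47.9%. The median peak width was 192 bp in both mutant libraries and 276 ± 5.66 bp in WT. A peak at a gene end was called for 5332.5 ± 431 genes in the mutant and 7888.5 ± 226 genes in WT. The mutant and WT libraries did not overlap in any of these values. An exact two-sided permutation test of 2 against 2 libraries gave p = 0.333 for each, the smallest it allows. The X chromosome held 14.6% of mutant peaks and 16.2% of WT peaks. Gene ends held 26.4% ± 0.994 of mutant peaks and 27.5% ± 0.216 of WT peaks, and this difference changed sign when short peaks were removed. Circular shifts of the peaks along the chromosomes put 14.1% to 17.0% of the peaks of a library at gene ends. The Jaccard index was 0.547 between the WT replicates, 0.416 between the mutant replicates and 0.298 to 0.342 between genotypes.

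Of the regions called in both WT libraries, 4641 were lost (27.1%), while 653 regions were gained and 8545 were kept. The other 2 splits of the same 4 libraries gave 405 to 835 regions on a side, so the gained regions were within that range and the lost regions were above it. The place of the gained regions depended on list length. With equal list lengths by width they rose above 982, the highest lost plus gained of another split of those lists. Without short peaks they fell, but the other splits were not counted again there. By gene ends, 1603 genes were lost, 114 gained and 3937 kept, against 78 to 143 in the other splits. Regions at gene ends were 27.2% of lost regions and 44.2% of kept regions (odds ratio 0.471, Fisher's exact test, adjusted p = 1.61e-83). Among gained regions they were 19.6% (odds ratio 0.307, exact test, adjusted p = 7.22e-37). The X chromosome held 18.4% of lost and 14.2% of kept regions (odds ratio 1.36, exact test, adjusted p = 1.30e-09). Narrow regions were lost most often, with 48.9% lost in the narrowest of 4 equal classes of WT width and 5.29% in the widest. Pooled over classes of WT width, the odds ratio of loss was 0.739 for gene ends (95% interval 0.677 to 0.808) and 1.33 for X (1.20 to 1.49). Of the kept regions, 67.4% were narrower in both mutant libraries than in both WT libraries, against 16.7% by chance and at most 8.94% in the other splits.

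**Figure D3:**
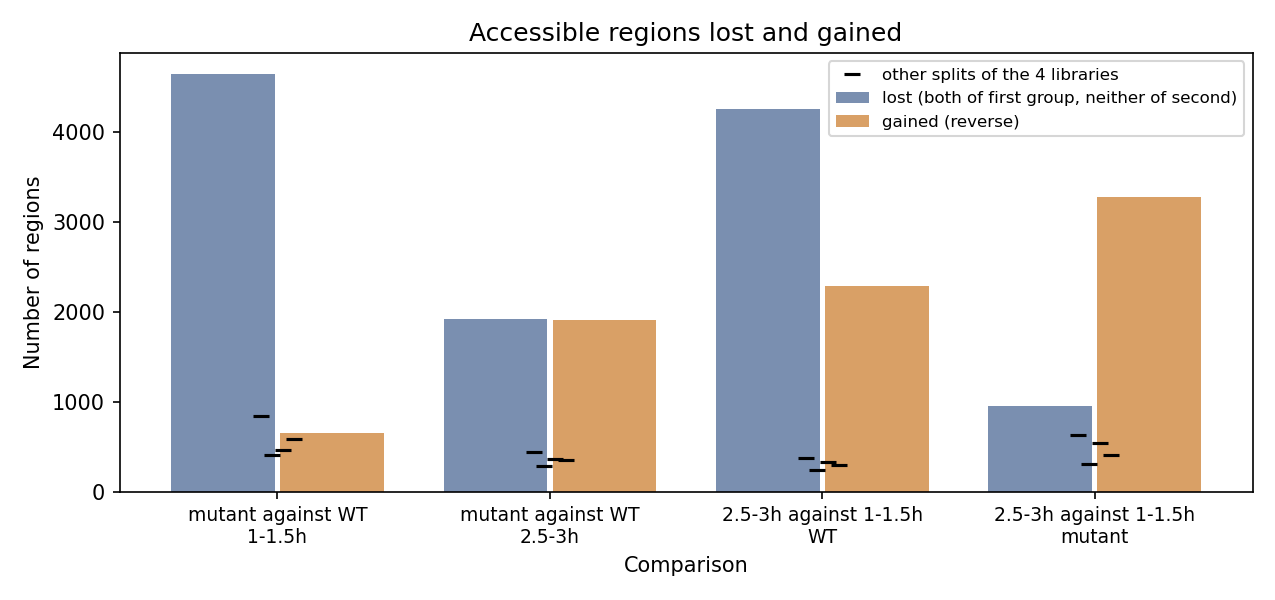
Regions lost and gained (bars, number of regions) in each comparison, with the counts given by the other splits of the same 4 libraries (dashes). The 4641 regions lost in the 1 to 1.5 h mutant lie far above the 405 to 835 of the other splits, and the 653 gained lie inside that range. The place of the gained regions depended on list length, and their number also on short peaks.

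The widest lost region lay inside Mi-2 (3L, 19885408 to 19887595), with a mean peak width of 1420.5 ± 269 bp in WT. The next were at gene ends of CG15922, Tango4 and Taf7, inside psq, E23 and Pkc98E, at 2 sites inside Hr4 on X, and between genes near CG42402. The E23 region (2L, 3338600 to 3339825) had a mean width of 1125 ± 123 bp in WT, and the second Hr4 region (X, 1991221 to 1992295) 999.5 ± 107 bp. Gained regions were narrower, with 636.5 ± 3.54 bp in the mutant for the widest, at Tmtc2. The others were at or inside Hacd1, br, CG34266, CG2663, rk (at 2 sites, one of them nearest NimC2), para and l(1)G0289, and 7201 bp from gus.

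Early zygotic genes, the genes of the first wave of transcription, lost a gene-end peak in 0 of 20 cases, against 29.0% of other genes (Fisher's exact test, adjusted p = 0.0385). Counted by separate regions the loss was 0 of 22 against 25.1% (exact test, adjusted p = 0.0973), so this call depended on the unit counted. It also missed the threshold with a gene-end window of 500 bp (exact test, adjusted p = 0.214). The early zygotic gene term gained a peak, of 178 ± 52.3 bp. None of 12 gap and terminal genes (exact test, adjusted p = 0.319) and none of 8 Hox genes lost a gene-end peak. Among 16 pair-rule and segment polarity genes only nkd did (exact test, adjusted p = 0.517), and among 19 dorsoventral genes ush and sog did (adjusted p = 0.562). Peaks at sna were 1538 and 1627 bp wide in the mutant and 1525 and 1847 bp in WT, and those at hb 342 and 381 bp against 417 and 443 bp. Other kept peaks narrowed more, as at slp1 (288 and 292 bp against 1027 and 839 bp) and Antp (130 and 130 bp against 496 and 556 bp). The peak at eve was wider in the mutant (1521 and 1490 bp against 653 and 1085 bp). Taken as a union, which was formed after the data were seen, the 5 patterning lists lost 5 of 81 regions (6.17%) against 25.3% of other regions (odds ratio 0.194, Fisher's exact p = 1.34e-05, not adjusted).

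**Figure D4:**
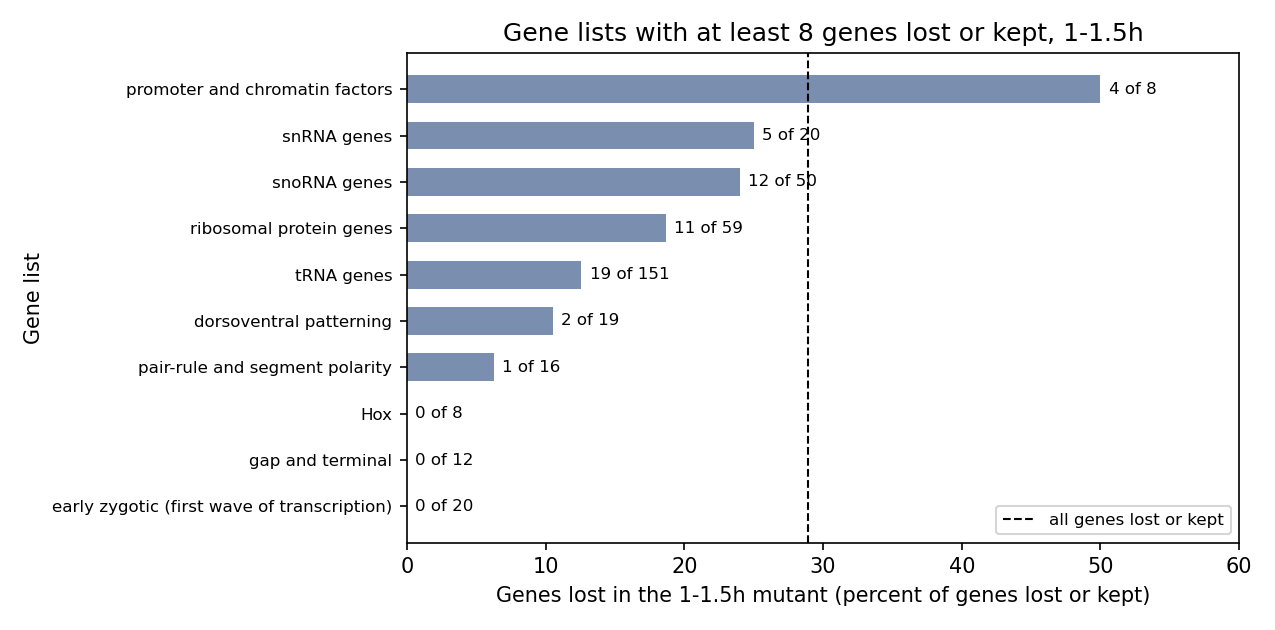
Share of genes in each list with at least 8 genes lost or kept whose gene-end peak was lost in the 1 to 1.5 h mutant, in percent of genes lost or kept (x axis), with the share of all genes as a dashed line. Early zygotic, gap and Hox genes lie at 0, and promoter and chromatin factors at 4 of 8, against 28.9% of all genes.

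The tRNA genes lost a gene-end peak in 19 of 151 cases, 12.6% against 29.4% of other genes (odds ratio 0.346, Fisher's exact test, adjusted p = 6.93e-05). The share of tRNA genes with a gene-end peak still fell, from 62.0% in WT to 51.4% in the mutant. It also fell at 2.5 to 3 h, from 65.4% to 53.6% (exact permutation p = 0.0556 over both windows, adjusted p = 0.185). Many tRNA genes share a region, and by separate regions 18 of 102 were lost, 17.6% against 25.2% (exact test, p = 0.0842, adjusted p = 0.561). With peaks of at least 200 bp the odds ratio by genes was 0.646 (exact test, adjusted p = 0.318), and with peaks anywhere within 2000 bp of the gene it was 1.02. The widest lost were at tRNA:Thr-AGT-1-2, tRNA:Leu-AAG-1-2, tRNA:Ser-AGA-2-1, tRNA:Asn-GTT-1-1, tRNA:Tyr-GTA-1-9 and tRNA:Asp-GTC-1-9, and peaks were gained at tRNA:Ala-AGC-2-10 and tRNA:Glu-TTC-1-3. The snRNA genes lost 5 of 20 (snRNA:U2:34ABb, snRNA:U6:96Ac, snRNA:U1:95Cc, snRNA:U6:96Ab and snRNA:U12). Ribosomal protein genes lost 11 of 59 (exact test, adjusted p = 0.562), the widest being RpS7 at 1010.5 ± 41.7 bp in WT, then RpL26, RpS15, RpS24, RpL37A and RpL36A. The snoRNA genes lost 12 of 50, the widest at scaRNA:MeU1:95C-A24, snoRNA:Or-CD9b, snoRNA:Psi28S-3436a, snoRNA:Me18S-C1831, snoRNA:Me5.8S-G74 and scaRNA:MeU2-C41, and gained snoRNA:Or-CD2. Promoter and chromatin factors lost 4 of 8 (Dref, Tbp, pho and BEAF-32, exact test, adjusted p = 0.960), a direction that reversed with a window of 500 bp (odds ratio 0.985) and with peaks anywhere within 2000 bp of the gene (odds ratio 0), and Integrator subunits 2 of 5 (asun and IntS3, with IntS11 itself counted as kept although its WT and mutant peaks share no region). Muscle genes lost 3 of 5 (Mlc2, up and bt), follicle cell genes 3 of 5 (Fcp3C, Vm26Aa and Cp18), maternal patterning genes 2 of 5 (dl and spz), and hemocyte, fat body and yolk genes 1 of 3 (Lsp1gamma). None was lost among 4 neural, 4 heat shock, 2 histone and 1 germline genes, and no gut enzyme gene was lost, gained or kept. Beyond the early zygotic and tRNA lists, no list passed an adjusted p of 0.05 for loss, and none did for gain. These calls changed with the processing. With common limits of 160 bp or peaks of at least 200 bp, 4 lists passed for loss, and with equal list lengths 1 did for gain.

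At 2.5 to 3 h, the comparison of mutant with WT addressed accessibility while zygotic genes are transcribed. Peak numbers and covered length were close, but 1919 regions were lost and 1907 gained, and fewer genes had a peak at a gene end. Regions inside E23 and Hr4 were lost in both windows, and a region inside zld, which encodes an activator of early zygotic genes, was lost at 2.5 to 3 h. A peak at a gene end of zld was still called in every library, at 808 and 717 bp in the mutant and 417 and 1015 bp in WT at 2.5 to 3 h. Regions inside fj and Hsc70-3 and at Elba3 were gained, although every library of 1 to 1.5 h called the fj and Hsc70-3 regions. Gap, pair-rule and dorsoventral genes lost no gene-end peak.

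The mutant libraries held 19515 ± 679 peaks (SD, n = 2) and the WT libraries 18721 ± 397, or 104% of WT, a difference that turned to -17.5 with peaks of at least 200 bp. They covered 8192 ± 203 kb and 8545 ± 239 kb, and the median widths were 339.5 ± 3.54 bp and 364.5 ± 0.707 bp. Gene ends held 30.3% ± 0.569 of mutant peaks and 34.2% ± 0.447 of WT peaks. A gene-end peak was called for 7304 ± 59.4 genes in the mutant and 8023 ± 83.4 in WT. The libraries of the genotypes did not overlap in any of these values, with p = 0.333 in each exact permutation test. Over both windows the mutant was lower in covered length, median width, share at gene ends and number of genes, each with p = 0.0556 (exact two-sided permutation test, 36 arrangements, the smallest it allows, adjusted p = 0.222). The number of peaks and the share on X did not move in one direction over both windows (exact permutation p = 0.333).

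The 1919 lost regions were 12.5% of those called in both WT libraries, and 11482 regions were kept. The other splits of these libraries gave 279 to 444 regions. By gene ends 678 genes were lost, 283 gained and 6027 kept, against 58 to 90 in the other splits. Regions at gene ends made up 27.6% of lost, 18.7% of gained and 43.2% of kept regions, and lost and gained regions differed (odds ratio 1.66, Fisher's exact test, adjusted p = 1.57e-10). Pooled over width classes the odds ratio of loss at gene ends was 0.873 (95% interval 0.775 to 0.983). The X chromosome held 20.1% of gained and 16.7% of kept regions (odds ratio 1.26, exact test, adjusted p = 0.000544), and 16.8% of lost regions (adjusted p = 0.921). Of regions called in all 4 WT libraries, 514 were lost in both windows, where 133 would be by chance (odds ratio 12.0, Fisher's exact p = 4.03e-222), though narrow regions are lost more often in either window and this test did not account for width. Another 102 regions were called in all 4 mutant libraries and in no WT library. The 616 regions that separated the genotypes in both windows compared with at most 118 in the other 17 splits of the 8 libraries within windows. The Jaccard index was 0.518 to 0.526 between genotypes, and 0.693 and 0.592 between WT and between mutant replicates.

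The widest lost regions were at UQCR-C1 (1224 ± 376 bp in WT), Bcat, E23, upSET, the overlap of CG46321 and Hr3, lncRNA:CR45290, zld (X, 19779143 to 19780258, 922.5 ± 24.7 bp), indra, tay and Hr4. The widest gained regions were at fj (2R, 18234075 to 18235880, 1725 ± 115 bp in the mutant), in CG33080 near AdamTS-B, in Hsc70-3, near gus, in rk near NimC2, in Dgp-1, para, Elba3 and l(1)G0289, and in Appl near mir-4960. The gus, rk, para and l(1)G0289 regions were among the widest gained in both windows. The fj, CG33080 and Hsc70-3 regions were called in all 4 libraries of 1 to 1.5 h and only the WT libraries of 2.5 to 3 h lacked them. The Dgp-1 region was also called in both WT libraries of 1 to 1.5 h.

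No list passed an adjusted p of 0.05 at 2.5 to 3 h by genes in the main setting. Follicle cell genes passed for gain with a gene-end window of 500 bp or peaks anywhere within 2000 bp of the gene. The tRNA genes passed for loss with peaks of at least 200 bp. The tRNA genes lost 27 of 170, 15.9% against 9.96% of other genes (Fisher's exact test, p = 0.0193, adjusted p = 0.295), the widest at tRNA:Tyr-GTA-1-7, tRNA:Arg-ACG-1-9, tRNA:Arg-ACG-1-10, tRNA:Ser-AGA-3-1, tRNA:Cys-GCA-1-2 and tRNA:Lys-CTT-1-13, and gained tRNA:Val-AAC-1-1. By separate regions 20 of 110 were lost, 18.2% against 9.46% (exact test, adjusted p = 0.0959). Follicle cell genes gained Vm26Ab (535 ± 156 bp) and Cp15, with 1 kept (exact test, adjusted p = 0.233). By separate regions 4 of 5 were gained against 6.62% (Fisher's exact test, adjusted p = 0.00374), so this result depended on the unit counted. Lost at gene ends were Bro among 24 early zygotic genes, Antp among 8 Hox genes, IntS9 and IntS10 among 8 Integrator subunits (IntS11 again counted as kept), and Stat92E (756.5 ± 0.707 bp), pho and CTCF among 11 promoter and chromatin factors. Of 72 ribosomal protein genes, RpS19b (1563.5 ± 3.54 bp), RpL34a and RpS18 were lost, and RpS12 was gained. Of 23 snRNA genes, snRNA:U6:96Ab, snRNA:U6:96Ac and snRNA:U2:38ABb were lost, and snRNA:U5:38ABa was gained. Of 84 snoRNA genes 10 were lost, the widest at snoRNA:Me28S-A3407a, snoRNA:Or-CD4, snoRNA:Psi28S-3378, snoRNA:Psi28S-1232, snoRNA:Me18S-G1358a and snoRNA:Psi28S-3327c, and snoRNA:Me28S-A774b, snoRNA:Or-aca5 and snoRNA:Edc3-a were gained. Peaks were also gained at Hsp26 (heat shock, 587.5 ± 114 bp), gd (maternal patterning), Lsp1gamma (fat body) and Ance (dorsoventral). No member of the muscle, neural, germline, histone or gut lists was lost or gained.

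The change in called peaks from 1 to 1.5 h to 2.5 to 3 h was compared within each genotype. In WT, regions inside L, kek5 and dve were lost with time, and regions at a snoRNA cluster in RpS7, at SmD3 and 2730 bp from hb were gained. Follicle cell genes such as Vm26Ab and Cp18 lost their gene-end peaks in WT. In the mutant more regions were gained than lost, and kept regions widened more than in WT. The 1 to 1.5 h mutant lists were shorter and narrower to begin with, and depth or fragment length could not be told apart from genotype there. With time the shortest peak rose from 100 and 101 bp to 148 and 149 bp in the mutant. In WT it rose from 120 and 122 bp to 154 and 156 bp. These changes are therefore not shown to be developmental.

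In WT, 4252 regions were lost, 2284 gained and 11155 kept, against 237 to 375 in the other splits. In the mutant, 953 were lost, 3276 gained and 8205 kept, against 312 to 630. With common limits of 160 bp the mutant loss fell, and with peaks of at least 200 bp it fell further. The other splits were not counted again under these limits, so these losses cannot be set against that range. The mutant gain rose in both cases. By gene ends, 612 genes were lost and 720 gained with time in WT, and 165 lost and 1365 gained in the mutant. Of kept regions, 49.2% were wider in both later libraries in WT, with a median width ratio of 1.13, and 80.6% in the mutant, with a ratio of 1.63. A later library called on average 4785.5 regions in WT and 7841 in the mutant that the earlier library it was paired with did not, over the 4 pairs of each genotype. The difference of 3056 had p = 0.111 (exact two-sided permutation test, 36 arrangements, smallest 0.0556). Of the regions lost in the mutant at 1 to 1.5 h, 39.8% were called in both WT libraries at 2.5 to 3 h and 46.0% in neither, and 23.8% were called in both mutant libraries and 55.9% in neither.

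The widest regions lost with time in WT were inside L (1455.5 ± 132 bp at 1 to 1.5 h), kek5, wtrw, rho-5 near CG33303, CG46467, Snoo, dve, CG18265 and Cpr76Bd, and at Nepl4. The widest gained were at RpS7 and its snoRNA genes (3R, 30206388 to 30207606, 1109.5 ± 88.4 bp at 2.5 to 3 h), in Ncc69, at SmD3 and mir-281-1, at CG42557, near lncRNA:CR45177, 2730 bp from hb (3R, 8700553 to 8701511, 909 ± 63.6 bp), in trol, at Marcal1 and CG3436, and in tay. The tay region was absent from all 4 libraries of 1 to 1.5 h and from both mutant libraries of 2.5 to 3 h.

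Follicle cell genes lost 5 of 6 gene-end peaks with time in WT (Vm26Ab, Cp18, Cp15, Vm34Ca and Cp19) against 9.30% of other genes (Fisher's exact test, adjusted p = 0.000785, and 0.0142 by separate regions). With a gene-end window of 100 bp no list passed for loss with time in WT. The snoRNA genes gained 22 with 58 kept, 27.5% against 10.6% (odds ratio 3.19, exact test, adjusted p = 0.000785), the widest at snoRNA:Me28S-A771, snoRNA:Or-CD2 and the RpS7 cluster. By separate regions the snoRNA gain was 6 of 79, 7.59% against 9.44% (exact test, adjusted p = 1), so this call depended on the unit counted. With peaks anywhere within 2000 bp of the gene the direction reversed (odds ratio 0.398). Maternal patterning genes lost snk, dl and spz with 3 kept (exact test, adjusted p = 0.132), and gut enzyme genes lost Jon65Ai and Jon25Bi (exact test, adjusted p = 0.117). Among Integrator subunits IntS9 and IntS10 gained a gene-end peak in WT and asun lost one, and among early zygotic genes tsg, term and Bro gained one. Ribosomal protein genes gained RpS19b, RpL7-like, RpL31, RpL7A and RpS19a and lost RpL8, RpL29, RpL32 and RpS12. The tRNA genes gained 17 and lost 9, with 152 kept, the widest of these at tRNA:Asp-GTC-1-8, tRNA:Arg-ACG-1-8, tRNA:Thr-AGT-1-5, tRNA:Thr-AGT-1-6, tRNA:Pro-CGG-3-1 and tRNA:Arg-TCG-3-2, all gained. Stat92E and CTCF (promoter and chromatin factors), Rbp9 (neural), pgc (germline) and His3:CG33866 (histone) gained a gene-end peak. Peaks were lost at sog and vnd (dorsoventral), bt (muscle), Lsp1gamma (fat body), snRNA:U12 and 4 snoRNA genes (scaRNA:MeU2-G25, snoRNA:Edc3-a, snoRNA:Irbp-a and snoRNA:Me28S-A774b). No gap, pair-rule, Hox or heat shock gene was lost or gained with time in WT.

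In the mutant, the tRNA genes lost a gene-end peak with time in 13 of 131 cases, 9.92% against 3.87% of other genes (odds ratio 2.73, Fisher's exact test, adjusted p = 0.0310). By separate regions 10 of 86 were lost, 11.6% against 5.07% (exact test, adjusted p = 0.262). They gained one in 15 of 133 cases, 11.3% against 26.4% (odds ratio 0.355, exact test, adjusted p = 0.00133), and by separate regions in 9 of 85, 10.6% against 19.8% (exact test, adjusted p = 0.501). Early zygotic genes gained a gene-end peak in 0 of 21 cases against 26.1% (exact test, adjusted p = 0.0310), and by separate regions in 2 of 25, 8% against 19.7% (exact test, adjusted p = 0.820). None of these 3 results passed by separate regions or with a gene-end window of 500 bp. The tRNA loss also missed the threshold without 1 to 1.5 h mutant replicate 1 (odds ratio 1.71, exact test, adjusted p = 0.296) or 2 (1.03, adjusted p = 1) and without 2.5 to 3 h mutant replicate 1 (2.18, adjusted p = 0.112). The early zygotic result missed it without 1 to 1.5 h mutant replicate 1 (odds ratio 0.283, exact test, adjusted p = 0.238). The tRNA loss reversed with peaks anywhere within 2000 bp of the gene (odds ratio 0.934). No other list passed an adjusted p of 0.05 with time in the mutant.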

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

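The tests of the peak caller's limits, of lower depth, of fragment length, of tRNA peak width and of separate regions were chosen after the results they concern had been seen.

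In 5 results the difference between mutant and WT had opposite directions in the 2 windows, without overlap of the genotypes' libraries in either. These results were picked by that rule, which alone fixes their p-values within a window and for the change between windows at the smallest possible. Those p-values therefore add no support. The shares of heat shock, dorsoventral, early zygotic and germline genes also changed direction, but their libraries did not stay apart in both windows. The number of peaks was lower in both mutant libraries at 1 to 1.5 h and higher in both at 2.5 to 3 h, and the mutant minus WT difference changed by 8164.5 peaks (exact permutation p = 0.0556, the smallest of 36 arrangements, adjusted p = 0.222). With peaks of at least 200 bp the later difference turned to -17.5 peaks, so the opposite direction depended on short peaks. The share of peaks on X changed by 1.97 percentage points in the same way (exact permutation p = 0.0556, adjusted p = 0.222). The other 3 results are counts of list members with a gene-end peak, with exact permutation p = 0.333 for mutant against WT in each window and p = 1 over both, and their change between windows was not tested. Follicle cell genes had 10 and 7 members in WT and 5 and 3 in the mutant at 1 to 1.5 h, and 2 and 1 against 8 and 3 at 2.5 to 3 h, a change of 8.5 in the difference. For maternal patterning genes the change was 3.5, from 6 and 6 against 3 and 5 to 3 and 4 against 5 and 5. For hemocyte, fat body and yolk genes it was 3, from 5 and 4 against 3 and 3 to 3 and 3 against 4 and 5. No biological or technical explanation was tested for the list counts.

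Fewer and narrower peaks in the mutant at 1 to 1.5 h could come from the peak caller, from depth or from the fragments sequenced. Lower limits add peaks (raising them to 160 bp took at least 4309 from each list), yet the mutant, with the lower limits, held at least 5109 fewer peaks than WT (largest gap between replicates 3137), and with common limits of 160 bp its median width stayed at least 55 bp below WT (largest gap 6 bp), which argues against the caller's limits as the whole cause. With all 4 lists taken to the same 15569 widest peaks, 3653 regions were lost or gained, against at most 982 in another split, but the shortest peak left was 214 bp in WT and at most 123 bp in the mutant, so peaks were removed up to a greater width in WT and lower depth cannot be told apart from a change in the sites. Shorter fragments in the mutant libraries cannot be told apart from the genotype, since the shortest peaks were at most 101 bp in the mutant and at least 120 bp in WT, with no overlap. An effect of mislocalized IntS11 therefore stays open beside a difference in depth or library preparation.

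Patterning and tRNA genes may have lost fewer peaks than other genes at 1 to 1.5 h because their peaks were wide in WT. They may also only seem to have done so because several genes share a region. The patterning genes had a median WT width of 571.5 bp against 449.5 bp for other genes, but sets matched on width lost on average 15.6 of 69 genes where they lost 3, and 0.0002 of 10000 sets lost as few. The tRNA genes had narrower peaks than other genes (median 317.5 bp against 454.5 bp, and 0.0001 of 10000 random sets were as narrow, the smallest share possible), which argues against wide peaks as the cause there. With each region counted once, 0.0008 of matched sets lost as few as the patterning genes (5 lost, 14.5 in matched sets), whereas for tRNA genes 0.0001 did (18 lost, 36.9 in matched sets) but the unmatched shares of 17.6% and 25.2% had an exact p of 0.0842, so shared regions cannot be told apart for tRNA genes. Reads shared between near-identical tRNA copies were not tested and stay open. The lists hold no signal height, so the sets were matched on width only. Strong peaks that outlast a lower depth in the mutant therefore cannot be told apart from a retained opening at patterning genes. Such a retained opening is a hypothesis found and tested on the same libraries.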

How the results depend on the processing

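The alternatives of 160 bp, at least 200 bp, equal lengths and the 2000 bp span were chosen after the data had been seen. Of 768 comparisons of 71 results with 18 alternatives, 634 kept direction and side of the threshold or stayed within the margin. Another 98 moved, 17 became weaker, 4 stronger and 15 reversed. No exact permutation test could pass the threshold, so results tested that way could change in size or direction but never in side. The 634 therefore include comparisons that were partly or wholly fixed beforehand, and their number does not measure robustness. Covered length, median width, number of genes with a gene-end peak and the odds ratios for gene ends kept their direction under all alternatives run. With replicate number as a block the values did not change, and p was 0.5 in each window and 0.125 or 0.5 over both. These block comparisons could only count as kept. Unless stated otherwise, the cause was not tested. All p-values of lists are from Fisher's exact tests.

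With a peak covering at least 50% of a region, 408 regions were gained in the mutant at 1 to 1.5 h, 3661 were gained with time in WT, and 496 were lost and 6428 gained with time in the mutant. With a gene-end window of 100 bp, 184 genes were gained at 2.5 to 3 h, 357 were lost with time in WT and 81 in the mutant, no list passed for loss with time in WT (0) and 1 for gain in the mutant, where early zygotic genes had odds ratio 0.221 (exact test, adjusted p = 0.257). The late difference in early zygotic share turned to 1.85 points, the snRNA odds ratio of early loss turned to 1.19, and the follicle cell loss with time had no finite odds ratio, since no member was kept. With 500 bp, 1 list passed for early loss (early zygotic genes had exact adjusted p = 0.214), 2 passed for late gain (follicle cell genes with odds ratio 79.3, adjusted p = 0.00105), and the promoter factor odds ratio turned to 0.985. With time, 953 genes were lost and 464 gained in WT, and 0 lists passed for loss or gain in the mutant, where early zygotic genes had odds ratio 0 (exact adjusted p = 0.307) and tRNA genes 2.30 for loss (0.194) and 0.542 for gain (0.202). The difference in early zygotic share at 1 to 1.5 h turned to 0.

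With common limits of 160 bp, the early difference in gene-end share turned to 0.0604 points, 267 regions and 67 genes were gained early, 316 regions were lost and 5006 gained with time in the mutant, and 4 lists passed for early loss. With time in the mutant, 36 genes were lost and 2200 gained, 0 lists passed for loss and 1 for gain, and tRNA genes had odds ratios 1.02 and 0.663 (exact adjusted p = 1 and 0.198), while 2 lists each passed for loss and gain in WT. With peaks of at least 200 bp, the late difference in peaks turned to -17.5 and the early one in gene-end share to 0.230. Then 194 regions and 59 genes were gained early, 2497 regions were lost with time in WT, 199 were lost and 5070 gained with time in the mutant, 4 lists passed for early loss and 1 for late loss (tRNA genes, odds ratio 2.09, exact test, adjusted p = 0.0424). The early tRNA result then had odds ratio 0.646 and exact adjusted p = 0.318. With time, 363 genes were lost in WT, 23 lost and 2481 gained in the mutant, 0 lists passed for loss and 4 for gain there, with tRNA genes at 1.83 and 0.694 (exact adjusted p = 1 and 0.464), and the difference in early zygotic share at 1 to 1.5 h turned to 0. These 2 alternatives remove short peaks, which were most frequent in the early mutant. With equal list lengths by width, 2178 regions were lost and 1475 gained early, 367 genes were gained early, 2112 regions and 319 genes were lost with time in WT, 1 list passed for early gain, 3 for loss and 2 for gain with time in WT, and the early tRNA share turned to 10.2 points higher in the mutant. By construction this removes the difference in peak number, by taking narrow peaks out of the longer lists.

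With a peak anywhere in the gene or within 2000 bp, 1 list passed for early loss and 3 for late gain (follicle cell genes with odds ratio 24.4, exact test, adjusted p = 0.000833). The early tRNA odds ratio turned to 1.02, that of promoter factors to 0 and that of snoRNA gain with time to 0.398, and early zygotic genes had exact adjusted p = 1. With time in WT 3 lists passed for loss and 0 for gain, and in the mutant 0 for loss and 1 for gain, with tRNA genes at 0.934 and 0.894 and early zygotic genes at 0 (each exact adjusted p = 1).

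Leaving out 1 library raised counts by construction, since fewer libraries had to match. Early, 6017 to 8817 regions were lost, most without WT replicate 2 of that window, and 1009 to 2937 gained, most without its mutant replicate 2, and 2067 to 2488 genes were lost and 173 to 401 gained. Late, 2812 to 3494 regions were lost and 2446 to 4461 gained, and 976 to 1059 genes were lost and 381 to 591 gained. With time, 5002 to 8438 regions were lost and 3109 to 3663 gained in WT, and 1345 to 4034 lost and 4344 to 6138 gained in the mutant. By gene ends, 781 to 1167 were lost and 966 to 1190 gained with time in WT, and 233 to 574 lost and 1816 to 2182 gained in the mutant. The early zygotic share differed by 0 to 14.8 points at 1 to 1.5 h and by -3.70 to 0 at 2.5 to 3 h. With time, 1 to 2 lists passed for loss in WT, 0 to 1 for loss and 1 to 2 for gain in the mutant, where the odds ratio was 1.03 to 2.35 for tRNA loss, 0.273 to 0.401 for tRNA gain and 0 to 0.283 for early zygotic gain. Lists that passed for late gain numbered 0 to 2, with follicle cell genes at odds ratio 65.4 (exact test, adjusted p = 9.48e-05) without mutant replicate 2 of 2.5 to 3 h.

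The alternatives that needed peak scores, summits or genome sequence (stricter thresholds of significance, equal lists by significance, summit regions and motif windows) were not run. The depth of the libraries is unknown, so its limits on these results could not be set.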

Other observations

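Of the tests here, those of the peak caller's limits, of regions that WT had at both ages and of regions within 1 Mb of IntS11 were chosen after their results had been seen.

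The profile of the mutant at 2.5 to 3 h might differ from WT because the embryos were younger, because of the peak caller or because the mutant line carries sequence variants. Of regions called in all 4 WT libraries, 803 were called in neither mutant library of 2.5 to 3 h, against at most 168 in another split of the 2.5 to 3 h libraries, more than a younger WT profile would give, and against the caller's limits, which were lower in the mutant and would add calls, stand at least 618 fewer genes with a gene-end peak than in WT (largest gap between replicates 118) and 1772 regions gained with common limits of 160 bp (at most 422 in another split). The mean Jaccard index with the 1 to 1.5 h WT libraries was 0.403 for the mutant and 0.429 for WT. This gap cannot decide about age. The index was also lower between mutant replicates of 2.5 to 3 h (0.592) than between WT replicates (0.693). Of the 4252 regions lost with time in WT, 13.1% were called in both mutant libraries of 2.5 to 3 h and 64.6% in neither. The 1 to 1.5 h mutant libraries called 19.7% in both and 50.2% in neither, so these shares cannot decide either. The 803 regions argue against a younger WT profile as the whole cause. An age effect at part of the regions stays open: 7 of the 10 widest of those 4252 were called in both later mutant libraries. Also, 29.2% of regions gained in the mutant were called in both earlier WT libraries (51.9% in neither). Of the 514 regions lost in both windows, 14.0% had a lost neighbour, above the 11.9% at the 95th percentile of 1000 shuffles within classes of width (mean 9.01%), which is consistent with variants in stretches, although neighbouring elements of a single gene would cluster too. Within 1 Mb of IntS11, 12 of 189 regions were lost in both windows, 6.35% against 4.58% elsewhere (Fisher's exact p = 0.223), so variants around the targeted gene cannot be told apart from other causes.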
